A study of Mus musculus with 64 samples.

How the data were processed

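Striatal RNA was measured in 32 mice on a C57BL/6NJ background, 16 with the Cyfip2 genotype N/- and 16 with the genotype N/N, with 8 mice of each sex per genotype. Per the labels' protocols, striatum punches were taken on Day 24 right after a 5 min test on the elevated plus maze (EPM), when the mice were 82 to 84 days old. Libraries were made with a stranded mRNA kit and read as 50 bp single-end reads on an Illumina HiSeq instrument. Each library was analysed as 2 sequencing runs, 64 runs in all. The labels' protocols speak of technical quadruplicates; any further runs were not used here. The series text states 8 mice per genotype, while the labels of the samples give 16 per genotype; the sample labels were followed. No diet or training group is labelled, so mice that differed in treatment within a genotype could not be told apart. Such a difference would add to the spread within a group. If it was unevenly divided over genotype or sex, it would also shift the differences between groups.

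The authors deposited whole-number counts of reads per gene, 1 table per sequencing run, with Entrez gene identifiers and no normalization. Per the submitters' processing notes, reads were checked with FastQC 0.11.3 and counted with featureCounts of the Subread package against mm10, and edgeR 3.8.6 and limma 3.22.7 are also named there. The series text names TopHat and HTSeq as aligner and counter in place of Subread and featureCounts. Which pair made the deposited counts is not settled by these sources, although the tables are named after featureCounts in the labels. The annotation version, the handling of reads with several matches and the use of strand in counting are not given in the sources used here. Counts of genes with near-identical copies (haemoglobins, ribosomal proteins with processed pseudogenes, Gm2223) and of overlapping genes on opposite strands (Xist and Tsix) are therefore uncertain.

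Each table held 27179 gene identifiers, of which 25275 matched a symbol in the RefSeq gene table of GRCm38.p6, the build also called mm10. The 1904 identifiers without a symbol held 0.766% of the counts and stayed in the library totals and tests. The coordinates are those of this table, counted from 1. Counts of the 2 runs of a library were summed per gene into 1 profile per mouse, after a chi-square comparison over genes with at least 10 summed counts. The chi-square per degree of freedom was 1.14 to 1.41 between 2 runs of a library and 3.62 to 82.5 between 2 mice of a group. The comparison of mice used summed profiles, which are deeper than single runs. Greater depth raises this ratio where samples differ, so the 2 ranges are not on the same scale. All 64 runs correlated best with the other run of their own mouse, with Pearson r of 0.994 to 0.996 across genes, which are not independent replicates. The runs of a library were therefore treated as technical and the mouse as the replicate. The labels do not say that mice came from separate litters. The 32 mice came from 20 cages, 10 of which held both genotypes (21 mice).

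The sequencing lanes named in the labels divide the libraries into batch A (10 N/- and 6 N/N mice) and batch B (6 N/- and 10 N/N mice). Genotype and batch were therefore partly confounded. Batch was a term in the tests on both batches, apart from the alternatives without it. No cage held mice of both batches, so lanes cannot be told apart from other differences between these sets of mice. Totals of the summed counts were 28.8 M to 33.8 M per mouse (median 31.8 M, where M is mega counts). At the median depth 1 CPM (reads of a gene per mega counts of the library) stands for about 31.8 counts, so that the counts of genes under 1 CPM carry a large counting error.

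Gene tests used edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (16776 of 23165 with at least 1 count), scaled by the trimmed mean of M values (TMM), and tested with the robust quasi-likelihood F test with batch, sex and genotype as terms. Effects of genotype within each sex, and their difference (the genotype by sex interaction), came from a fit with 4 genotype and sex groups and batch. P-values were adjusted over genes by the method of Benjamini and Hochberg with a threshold of 0.05. Standard errors (SE) of log2 fold changes were obtained by dividing the absolute log2 fold change by the square root of F. Fold changes are N/- over N/N and male over female. Intervals cover 95%. CPM values are scaled by the TMM factors and given as mean ± SD. Cyfip2 and En2 were also tested by two-sided permutation tests of the difference in mean log2 CPM (prior count 2) with 100000 resamples, over all mice and within batch and sex.

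Gene lists (31 lists, 500 symbols, of which 2 had no match) were tested with camera of limma 3.58.1 on voom values with a preset correlation between genes of 0.01, with camera and an estimated correlation, and with fry, in each case adjusted over the 31 lists of a contrast. They cover the WAVE regulatory complex, fragile X protein (FMRP) partners and translation, actin regulators, myelin, oligodendrocyte precursors, cholesterol synthesis, astrocytes, microglia, endothelial and mural cells, choroid plexus, ependyma, haemoglobin, pan striatal, D1 and D2 projection neurons, striatal interneurons, cortical glutamatergic neurons, thalamus and other neighbouring regions, immediate early, glucocorticoid responsive, clock, opioid, dopamine and feeding genes, excitatory and inhibitory synapses, heat shock, oxidative phosphorylation, ribosomal proteins, and Y-linked and X-linked genes. A list score is the mean over its members of log2 CPM centred on the mean of the mice.

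The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named Cyfip2 and each tested WAVE member. For the genotype effect it named the 10 genes per direction with the smallest p past the threshold, or 5 per direction said not to pass where fewer passed. It named the 4 members with the smallest p of each list whose camera test passed. For sex it named the Y-linked genes of the list, Xist and the 8 further genes per direction with the smallest p past the threshold. It also named the 5 genes with the smallest p for the interaction and for each sex, the 4 tested genes nearest to Cyfip2, and 2 members each of the myelin, immediate early, D1, D2 and opioid lists where these did not pass. Some genes that this rule names are not reported here.

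Each fit was tested on simulated counts with 100 genes changed by 1.2-fold and 100 by 1.5-fold. For genotype (16702 genes tested) 56% and 90% of these were recovered, with 9 false calls among 155. For sex (16703 genes) the shares were 57% and 90%, with 4 false calls among 151. With the change in N/- males alone, the test within males recovered 36% and 75% with 3 false calls among 114, and the interaction test recovered 11% and 58% with 7 false calls among 76 (16702 genes each). A simulated list of 20 genes shifted by 1.2-fold was found by camera with the preset and with the estimated correlation, and none of the other lists was called. The simulated genes were drawn independently, whereas the correlation estimated within the real lists had a median of 0.318 for genotype. False calls among correlated genes could therefore not show in this simulation. Many genes were changed at once, which makes the adjusted threshold easier to reach. Where few genes differ, the shares recovered may be lower.

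Alternatives were other scalings (relative log expression, upper quartile), DESeq2 1.42.0, limma voom with quality weights, no filter on low counts and a filter of CPM above 1 in 16 mice, no batch term, no sex term, each run alone, cage as a random effect or a fixed block, each batch alone, 5 surrogate variables from sva 3.50.0, a threshold of 0.10, no robust estimation, each mouse left out in turn, other windows around Cyfip2, and a permutation within batch and sex. Chosen after the data were seen were the cortical list score as a covariate, the removal of the 4 mice with the highest cortical list score, and list tests without mouse 3 or mouse 12.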

Results

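RNA sequencing counts from the striatum were compared between 16 mice with the Cyfip2 genotype N/- and 16 with the genotype N/N, 8 males and 8 females of each. C57BL/6N mice are known to carry a missense variant of Cyfip2, the N allele, and the minus sign marks a null allele. Per the labels, N/N mice are prone and N/- mice resistant to binge eating. Summed counts per mouse were 28.8 M to 33.8 M, with a median of 31.2 M in N/- and 31.8 M in N/N mice (M, mega counts), and 19341 to 20092 genes had at least 1 count. Mitochondrial genes took 5.83% to 10.4% of the counts, and the TMM factors were 0.931 to 1.03, with the highest share and the lowest factor in mouse 12, an N/- female.

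The first comparison checked the targeted gene in every mouse. Cyfip2 (Entrez 76884, chromosome 11, 46193849 to 46312859, mm10), a subunit of the WAVE regulatory complex that links Rac signalling to actin branching, fell from 1068.5 ± 96.4 CPM (SD, n = 16) in N/N mice to 596.9 ± 43.9 CPM (SD, n = 16) in N/- mice. The N/- level was 55.9% of the N/N level (95% interval 52.6% to 59.4%), a log2 fold change of -0.84 (SE 0.04), with an adjusted p of 4.93e-15 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All 16 N/- mice, at 509 to 653 CPM, lay below all 16 N/N mice, at 929 to 1278 CPM. The permutation p was 1e-05, the smallest that 100000 resamples can give, over all mice and also within batch and sex. The log2 fold change was -0.91 (SE 0.06) in batch A and -0.78 (SE 0.06) in batch B. Counts were summed over the whole gene, and which exons the minus allele lacks is not given in the sources used here.

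**Figure D1:**
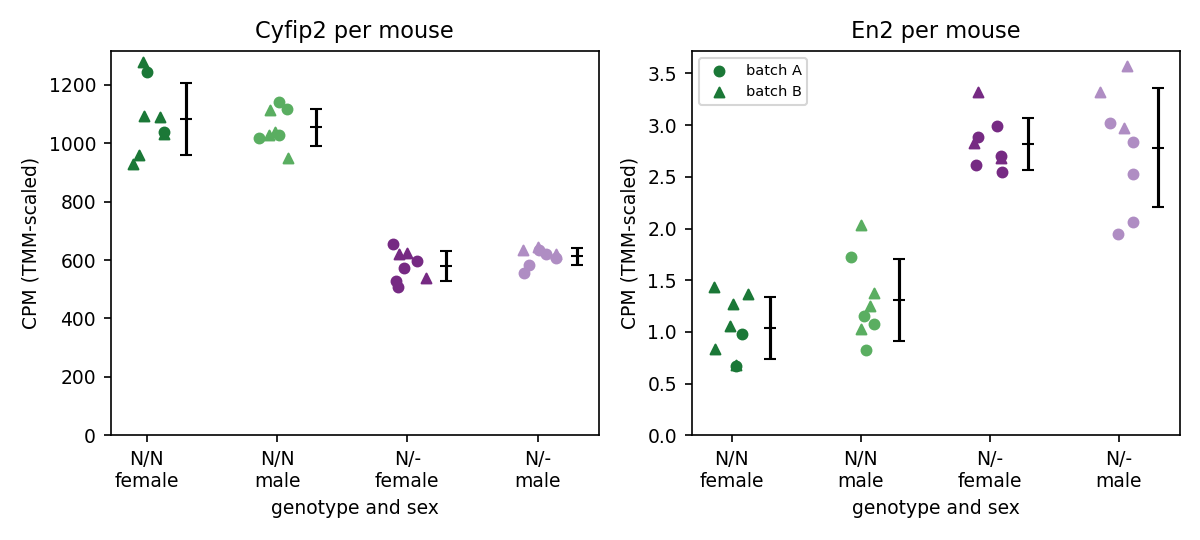
CPM of Cyfip2 and En2 (TMM-scaled) in each of the 32 mice by genotype and sex (circles, batch A; triangles, batch B; bars, mean ± SD, n = 8 per group). The N/- mice lie at 509 to 653 CPM for Cyfip2, all below the N/N mice, and at 1.95 to 3.57 CPM for En2, against 0.672 to 2.03 CPM in N/N mice.

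The genotype comparison asked which transcripts accompany the loss of 1 Cyfip2 copy. Besides Cyfip2, En2 (Entrez 13799, chromosome 5, 28165696 to 28172190), a homeobox transcription factor known for patterning the midbrain and hindbrain, was the only gene past the threshold among 16776 tested. En2 rose from 1.17 ± 0.37 to 2.80 ± 0.43 CPM (SD, n = 16 each), a 2.50-fold difference (95% interval 2.14 to 2.92). The raw counts per mouse were 20 to 68 in N/N and 59 to 116 in N/- mice. Its log2 fold change was 1.32 (SE 0.11), with an adjusted p of 3.35e-09 by edgeR's quasi-likelihood test, and the permutation p was again 1e-05, the smallest possible. The highest N/N mouse, at 2.03 CPM, overlapped the lowest N/- mouse, at 1.95 CPM. Within batches the log2 fold change was 1.29 (SE 0.18) in A and 1.31 (SE 0.15) in B. In all, 1083 genes had an unadjusted p under 0.05, 727 higher and 356 lower in N/- mice, against 838.8 from chance alone. The same 838.8 applied to 899 genes by sex, 587 for genotype in males, 626 in females and 292 for the interaction. Genes vary together, so this number does not measure how far such counts spread by chance. No excess is read from them.

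The remaining genes with the smallest p did not pass the adjustment. Higher in N/- mice, without passing, were Epha3, an ephrin receptor (log2 fold change 0.26, SE 0.06), Napepld, an enzyme that makes N-acylethanolamines (0.27, SE 0.06), Gabrb2, a GABA-A receptor subunit (0.16, SE 0.04), and Msln, which encodes mesothelin (0.96, SE 0.24). Msln stood at only 0.249 ± 0.107 CPM in N/N and 0.497 ± 0.224 CPM in N/- mice (SD, n = 16 each). Lower without passing were 3110039M20Rik (-0.21, SE 0.05), 1 gene without a symbol (Entrez100502649, -0.27, SE 0.07), the palmitoyltransferase gene Zdhhc18 (-0.11, SE 0.03) and the exonuclease gene Trex1 (-0.11, SE 0.03). Their adjusted p by edgeR's quasi-likelihood test was 0.580 for Epha3, 0.690 for Napepld and 0.714 for each of the others.

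The other members of the WAVE complex showed no matching difference. Cyfip1, the paralog of Cyfip2, had a log2 fold change of 0.03 (SE 0.03), Nckap1 0.03 (SE 0.03), Wasf1 0.0027 (SE 0.04), Wasf3 0.02 (SE 0.04), Abi1 0.00052 (SE 0.03) and Abi2 0.03 (SE 0.02). Nckap1l stood at -0.03 (SE 0.05), Wasf2 at -0.0058 (SE 0.04), Abi3 at -0.04 (SE 0.06) and Brk1 at -0.02 (SE 0.04). Of the 11 members, 1 (Cyfip2) passed over all genes and 1 adjusted over the list alone. The list did not pass camera (adjusted p = 0.102; median log2 fold change 0.00052, mean -0.07). Fry's test for change in either direction gave an adjusted p of 5.22e-09, and Cyfip2 was the only member with an unadjusted p under 0.05.

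Genes near Cyfip2 were examined because a targeted allele can alter its neighbours. Among the 12 tested genes that start within 1 Mb, 0 passed edgeR's test over all genes or adjusted over these genes alone, and 2 had an unadjusted p under 0.05. These were Lsm11, a subunit of the histone pre-mRNA processing complex (log2 fold change 0.32, SE 0.12, adjusted p = 0.0998 over these genes), and Med7, a Mediator subunit (-0.07, SE 0.03, adjusted p = 0.242). Both were named after their values were seen. Gabrb2 (above), which did not pass, starts at 42419515 on the same chromosome, outside the windows examined. Among the nearest tested genes were Nipal4 (-0.05, SE 0.10), Adam19 (0.05, SE 0.04) and Fndc9 (0.09, SE 0.09). Over all genes DESeq2 and limma voom called 0 genes by genotype beyond Cyfip2 and En2; the adjustment over the window alone was not repeated with them.

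Lists of markers for striatal projection neurons lay lower in N/- mice. All 18 pan striatal projection neuron genes had a negative log2 fold change (median -0.12; camera adjusted p = 9.10e-09, and adjusted p = 0.458 with an estimated correlation). They included Ptpn5, a striatum-enriched tyrosine phosphatase (-0.16, SE 0.06), Ppp1r1b, the dopamine-regulated phosphatase inhibitor (-0.19, SE 0.08), Dclk3 (-0.13, SE 0.06) and the G protein subunit gene Gng7 (-0.16, SE 0.08). Of the D2 projection neuron genes, 8 of 10 were negative (median -0.14; camera adjusted p = 0.00177, and adjusted p = 0.458 with an estimated correlation). Penk, the enkephalin precursor, stood at -0.21 (SE 0.09), the dopamine receptor gene Drd2 at -0.18 (SE 0.08), Upb1 at -0.21 (SE 0.10) and the orphan receptor gene Gpr6 at -0.15 (SE 0.08). Of the D1 projection neuron genes, 9 of 10 were negative (median -0.09; camera adjusted p = 0.00726, and adjusted p = 0.574 with an estimated correlation). Among these were Tac1, the substance P precursor (-0.21, SE 0.08), Pdyn, the dynorphin precursor (-0.24, SE 0.10), and Slc35d3 (-0.18, SE 0.08), whereas Lingo2, a membrane protein gene, had the opposite sign (0.18, SE 0.06). Without mouse 3, an N/N mouse labelled female with 36 Xist counts, the D1 list no longer passed (adjusted p = 0.0551). Adjusted over the list alone 1 gene passed in these 3 lists, Lingo2, and over all genes 0 passed by edgeR; 3, 3 and 4 members of the pan striatal, D2 and D1 lists had an unadjusted p under 0.05. The dopamine signalling list shares 5 of its 12 tested members with them (Ppp1r1b, Drd1, Drd2, Gnal and Adcy5) and also lay lower (9 of 12 negative, median -0.10, camera adjusted p = 0.00140, and adjusted p = 0.458 with an estimated correlation), with Adcy5, a striatal adenylyl cyclase, at -0.14 (SE 0.07) and Ddc, dopa decarboxylase, at -0.12 (SE 0.06).

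Cortical glutamatergic neuron markers lay higher in N/- mice, with 14 of 16 positive (median 0.27; camera adjusted p = 0.000878, and adjusted p = 0.574 with an estimated correlation). Cux2, a transcription factor of upper cortical layers, stood at 0.35 (SE 0.14), Mef2c at 0.23 (SE 0.09), Emx1 at 0.45 (SE 0.21) and Slc17a7, a vesicular glutamate transporter gene, at 0.37 (SE 0.19). Slc17a7 measured 408 ± 104 CPM in N/N and 524 ± 239 CPM in N/- mice (SD, n = 16 each). The 4 mice with the highest cortical list score were all N/- mice of batch A. Without them the D1 (adjusted p = 0.220), D2 (0.142) and cortical (0.316) lists no longer passed, the last by construction in part since these mice were chosen by its score, while the pan striatal (0.00643) and dopamine (0.0392) lists did. The choice may bear on the D1 and D2 lists too. Only N/- mice were removed, and the projection neuron score was lower where the cortical score was higher (below). With the cortical score as a covariate the pan striatal list passed as well (adjusted p = 0.00352), and the D1 (0.345), D2 (0.0721) and dopamine (0.0521) lists did not. With surrogate variables none of the pan striatal (adjusted p = 0.316), D1 (0.880), D2 (0.316), dopamine (0.265) and cortical (0.893) lists passed. In batch A alone the cortical list did not pass (adjusted p = 0.0878), and in batch B alone the D1 (0.194) and D2 (0.748) lists did not. Across mice of 1 genotype the projection neuron score was lower where the cortical score was higher, with Pearson r of -0.76 in N/- (permutation p = 0.00056; Spearman rho -0.71, p = 0.00288; n = 16) and -0.76 in N/N mice (permutation p = 0.00072; rho -0.71, p = 0.0026; n = 16), both 0.00108 after adjustment over 3 relations. Without the 2 mice farthest from the median on the cortical axis r was -0.77 and -0.69. Within batch A r was -0.87 in 10 N/- mice (permutation p = 0.00088) and -0.92 in 6 N/N mice (exact permutation p = 0.0167). In batch B r was -0.27 in 6 N/- mice (exact permutation p = 0.601) and -0.59 in 10 N/N mice (permutation p = 0.0766), so the relation did not pass there. The genotype difference in projection neuron score was -0.12 (SE 0.07) over all mice, -0.22 (SE 0.12) in batch A and -0.03 (SE 0.06) in batch B.

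**Figure D2:**
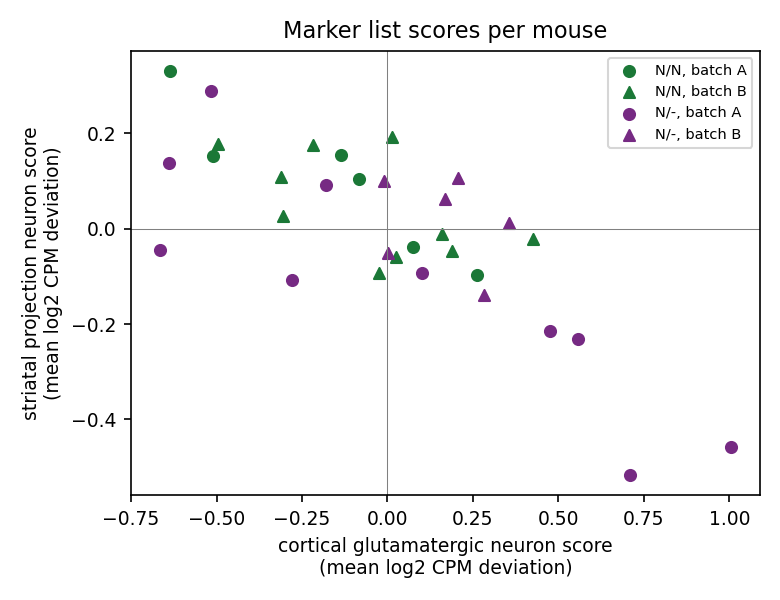
Projection neuron list score against cortical list score (both mean centred log2 CPM) for each of the 32 mice, by genotype and batch. The projection neuron score is lower where the cortical score is higher (r of -0.76 in each genotype), and the 4 highest cortical scores, 0.48 to 1.01, belong to N/- mice of batch A.

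Other cell type lists differed too. All 16 endothelial and mural genes were negative in N/- mice (median -0.07; camera adjusted p = 3.04e-05, and adjusted p = 0.458 with an estimated correlation), among them the smooth muscle genes Tagln (-0.19, SE 0.07) and Acta2 (-0.24, SE 0.09), the pericyte receptor gene Pdgfrb (-0.11, SE 0.05) and Ly6c1 (-0.13, SE 0.06). All 5 haemoglobin-related genes were negative (median -0.31; camera adjusted p = 0.00150, and adjusted p = 0.458 with an estimated correlation). Of these 3 passed adjusted over the list alone and 0 over all genes, with Hbb-bs at -0.51 (SE 0.20), Hba-a2 at -0.31 (SE 0.12), Hba-a1 at -0.31 (SE 0.13) and Hbb-b1 at -0.28 (SE 0.15). The haemoglobin copies are nearly identical, so the division of reads among them is uncertain. Microglial genes were negative in 15 of 16 cases (median -0.04; camera adjusted p = 0.0269, and adjusted p = 0.820 with an estimated correlation), with the complement genes C1qb at -0.09 (SE 0.06) and C1qa at -0.08 (SE 0.06), Tyrobp at -0.10 (SE 0.07) and Tmem119 at -0.07 (SE 0.05). The striatal interneuron list passed downwards (median -0.06, but mean 0.02; camera adjusted p = 0.0414, and adjusted p = 0.458 with an estimated correlation). Its members moved apart: the cholinergic genes Slc18a3 (-0.26, SE 0.09) and Chat (-0.21, SE 0.08) and Npy (-0.14, SE 0.05) were lower, and the neuropeptide gene Vip was higher (0.56, SE 0.22), without passing over all genes. Without mouse 3 the microglial (adjusted p = 0.134) and interneuron (0.108) lists no longer passed, nor did the interneuron list without mouse 12 (0.0580), an N/- female with outlying ribosomal and microglial scores. With surrogate variables the microglial list turned in direction (0.943), and the interneuron list did not pass in batch A (0.240) or batch B (0.121) alone. Nor did the interneuron list pass with cage as a random effect (adjusted p = 0.0856). Adjusted over the list alone 0 members of the endothelial, microglial and interneuron lists passed.

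Among pathway lists, 35 of 38 ribosomal protein genes were negative (median -0.03; camera adjusted p = 0.00782, and adjusted p = 0.878 with an estimated correlation). Rps19 stood at -0.12 (SE 0.07), Rps2 at -0.09 (SE 0.07) and Rps23 at -0.28 (SE 0.18), while Rpl5 was positive (0.13, SE 0.07), and their pseudogenes leave these counts uncertain. Cholesterol synthesis genes were positive in 16 of 20 cases (median 0.04; camera adjusted p = 0.0356, and adjusted p = 0.851 with an estimated correlation), with Hsd17b7 at 0.10 (SE 0.04), Sc5d at 0.07 (SE 0.04) and Lss at 0.07 (SE 0.05). The direction of the cholesterol list turned without the 4 mice of high cortical score (adjusted p = 0.605), and with surrogate variables those of the cholesterol and ribosomal lists did (0.880 each). The X-linked list passed upwards with only 4 of 8 members positive (median 0.03; camera adjusted p = 0.0451, and adjusted p = 0.574 with an estimated correlation), with Ddx3x at 0.08 (SE 0.03), Kdm6a at 0.07 (SE 0.05), Eif2s3x at 0.06 (SE 0.05) and Tsix at 0.14 (SE 0.25). The X-linked list did not pass in batch A (adjusted p = 0.195) or batch B (0.0939) alone or with cage as a random effect (0.0815), nor the ribosomal list in batch A (0.964). Without mouse 3 the X-linked (adjusted p = 0.723) and cholesterol synthesis (0.136) lists no longer passed, nor did they without mouse 12 (0.0580 and 0.0538). Adjusted over the list alone 0 members of these 3 lists passed, as over all genes. In all, 12 of 31 lists passed camera with the preset correlation, 3 up and 9 down, 0 passed with an estimated correlation and 0 passed fry's directional test.

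The other lists did not pass camera by genotype. Myelin genes had a median of 0.0094 over 30 members (adjusted p = 0.882), with Enpp2 at 0.06 (SE 0.07) and Apod at -0.06 (SE 0.08). Immediate early genes had a median of 0.02 (adjusted p = 0.740), with Fos at 0.41 (SE 0.35) and Fosb at -0.09 (SE 0.07), and opioid genes a median of -0.0092 (adjusted p = 0.789). The inhibitory synapse list had a median of 0.02 (adjusted p = 0.0672), with 3 members higher adjusted over the list alone and 0 over all genes, and the clock list a median of -0.03 (adjusted p = 0.0536). Without mouse 3 the inhibitory synapse (adjusted p = 0.0105) and excitatory synapse (0.0154) lists passed upwards with the preset correlation. Over all mice they had an adjusted p = 0.649 and 0.820 with an estimated correlation, and in batch A alone the excitatory synapse list had the opposite direction (0.959). Medians were 0.04 for excitatory synapse (adjusted p = 0.127), -0.01 for oxidative phosphorylation (0.169, and 0.00162 without mouse 12, where it passed downwards), 0.19 for choroid plexus (0.252), -0.0039 for astrocytes (0.431) and -0.0019 for glucocorticoid responsive genes (0.481). They were 0.07 for feeding neuropeptides and receptors (adjusted p = 0.734), 0.03 for ependyma (0.740), -0.0076 for heat shock (0.740), 0.07 for thalamus and other neighbouring regions (0.740) and -0.00092 for actin regulators (0.836). Oligodendrocyte precursor genes had a median of -0.0076 (adjusted p = 0.924), FMRP partners and translation 0.0087 (0.924) and Y-linked genes 0.13 (0.951). The camera direction was down against a positive median and mean for the ependymal, immediate early and myelin lists. It was down against a positive mean for the astrocyte and glucocorticoid lists, and up against a negative median for the actin list. Adjusted over the list alone 0 members of these lists passed, apart from the inhibitory synapse list.

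The genotype effect was next estimated within each sex, 8 against 8 mice. In males Cyfip2 fell by 0.78 on the log2 scale (SE 0.06; 1054 ± 63.9 to 612.9 ± 29.2 CPM, SD, n = 8) and En2 rose by 1.12 (SE 0.15). In females Cyfip2 fell by 0.90 (SE 0.06; 1083.1 ± 123.9 to 580.8 ± 51.9 CPM, SD, n = 8) and En2 rose by 1.55 (SE 0.16). These were the 2 genes past the threshold in each sex by edgeR's quasi-likelihood test (En2 adjusted p = 0.000136 in males and 3.39e-07 in females), with 587 genes at an unadjusted p under 0.05 in males and 626 in females. The En2 call in males was lost when the first run of each library was used alone (adjusted p = 0.0565). Among the next in males, without passing, were 3110039M20Rik (-0.30, SE 0.07) and Pcdhac1, a clustered protocadherin (0.46, SE 0.11). In females these were Tnfsf9, a tumour necrosis factor superfamily ligand (-0.64, SE 0.14), Cry1, a clock repressor (-0.35, SE 0.08), and Dpagt1, an enzyme of N-glycosylation (-0.18, SE 0.05).

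No gene showed a genotype effect that differed between the sexes past the threshold. The interaction test of edgeR gave 0 genes, with 292 at an unadjusted p under 0.05, and DESeq2 and limma voom also gave 0. The smallest p belonged to Bak1, a mediator of apoptosis, whose genotype effect was -0.12 in males and 0.08 in females (difference -0.20, SE 0.05), followed by the transcriptional repressor gene Zbtb7a (0.10 and -0.14; difference 0.24, SE 0.07). Peli3, a ubiquitin ligase gene (difference 0.23, SE 0.07), Zfp444, a zinc finger gene (0.26, SE 0.07), and Ppcs, an enzyme of coenzyme A synthesis (0.45, SE 0.13), came next. Among gene lists, 13 of 31 passed camera for the interaction with the preset correlation, 8 up and 5 down, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.445. Without mouse 12 the ribosomal (adjusted p = 0.337) and microglial (0.679) lists no longer passed. Immediate early genes had the smallest p (18 of 20 differences positive, median 0.26; camera adjusted p = 1.29e-05, and adjusted p = 0.445 with an estimated correlation). Their median genotype effect was 0.13 in males and -0.11 in females. In batch B alone the difference had the opposite sign (adjusted p = 0.876).

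The sex comparison found 18 genes. The Y-linked genes of the list rose in males: Ddx3y, an RNA helicase gene, to 82.5 ± 7.19 CPM against 0.673 ± 0.75 CPM in females (SD, n = 16 each; log2 fold change 6.96, SE 0.25), Uty (6.53, SE 0.19), the histone demethylase gene Kdm5d (6.96, SE 0.24), and Eif2s3y, a translation initiation factor gene (7.002, SE 0.26). The lowest male, at 72.0 CPM of Ddx3y, lay above the highest female, at 2.27 CPM. Xist, the RNA that coats the inactive X chromosome, was lower in males (-7.84, SE 0.59), at 5.196 ± 6.03 CPM against 1203 ± 384 CPM in females (SD, n = 16 each). In 15 of 16 females Xist was at 825 to 1651 CPM, and in mouse 3 it was at 1.21 CPM. Higher in females were also the X-linked genes Ddx3x (-0.33, SE 0.03), Eif2s3x (-0.49, SE 0.05), Kdm6a (-0.46, SE 0.05), Kdm5c (-0.23, SE 0.04), Gm2223 (-0.57, SE 0.05), Pbdc1 (-0.30, SE 0.05) and 5530601H04Rik (-0.36, SE 0.07). Among autosomal genes, Fcrls, a microglial Fc receptor-like gene, was higher in females (33.3 ± 3.28 against 27.5 ± 3.15 CPM, SD, n = 16 each; -0.29, SE 0.05).

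**Figure D3:**
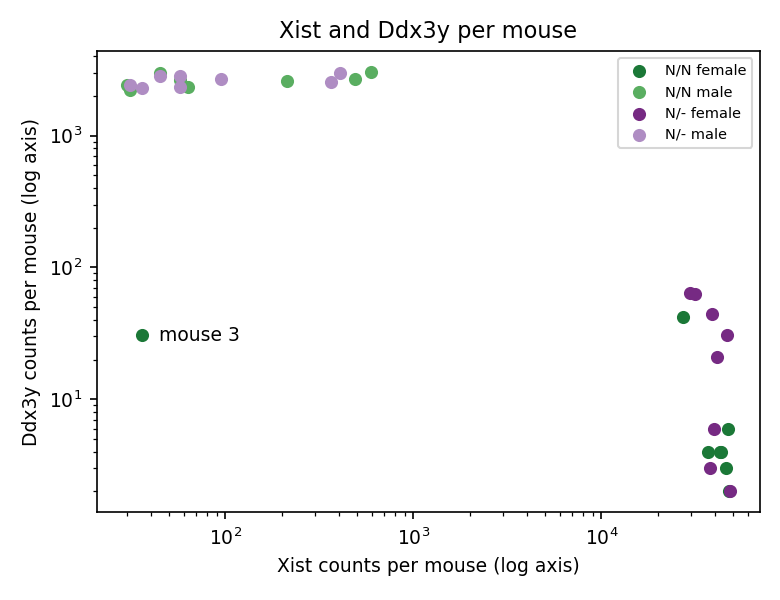
Ddx3y counts (vertical) against Xist counts (horizontal) for each of the 32 mice on log axes, by genotype and labelled sex. The males lie at 30 to 598 Xist and 2200 to 3050 Ddx3y counts; mouse 3, labelled female, lies at 36 Xist and 31 Ddx3y counts, apart from the other 15 females at 27239 to 48029 Xist counts.

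By chromosome the 18 genes were 5 of 5 tested Y-linked, 9 of 579 X-linked and 4 of 15687 autosomal genes, with 899 genes at an unadjusted p under 0.05. The genes beyond the naming rule, given after their values were seen, were Uba1y (6.89, SE 0.41), Chrdl1, a bone morphogenetic protein antagonist (-0.33, SE 0.06), Myo3b, an unconventional myosin (-0.43, SE 0.08), Vdr, the vitamin D receptor gene (-0.68, SE 0.14), and Tmem174 (-1.28, SE 0.26). Uba1y stood at the log2 CPM of 0 counts (-3.98) in every female, so the size of its fold change is poorly determined. Tmem174 (-3.40 to -0.72) and Vdr (-1.41 to 0.50) were low in log2 CPM. These 3 calls were lost with the filter of CPM above 1 in 16 mice. Tmem174 and Uba1y were also lost in each run alone, and Vdr and Pbdc1 in the first. The adjusted p by edgeR's quasi-likelihood test ranged from 3.04e-22 for Uty to 0.0268 for Tmem174 and Vdr. Batch A alone, with 7 females and 9 males, gave 7 genes, and batch B alone, with 9 females and 7 males, gave 16. With cage as a random effect 13 of the 18 genes passed, and 5530601H04Rik (adjusted p = 0.0573), Chrdl1, Myo3b, Tmem174 and Vdr did not. DESeq2 called 28 genes and the fit with surrogate variables 80, all 18 included in each.

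Of the lists, 7 passed camera for sex, and the Y-linked and X-linked lists held with an estimated correlation (adjusted p = 1.41e-09 and 2.50e-07). In the Y-linked list 4 of 4 and in the X-linked list 6 of 8 members passed over all genes, and as many adjusted over the list alone. Cholesterol synthesis genes lay lower in males (18 of 20 negative, median -0.03; camera adjusted p = 0.00442, and adjusted p = 0.971 with an estimated correlation), with Msmo1 at -0.13 (SE 0.05), Hmgcs1 at -0.13 (SE 0.06), Hsd17b7 at -0.10 (SE 0.04) and Cyp51 at -0.10 (SE 0.05). In batch A alone the cholesterol list had the opposite direction (adjusted p = 0.457), and without the 4 mice of high cortical score it did not pass (0.0505). Excitatory synapse genes also lay lower (22 of 27 negative, median -0.04; camera adjusted p = 0.0308, and adjusted p = 0.949 with an estimated correlation), with the scaffold genes Dlg4 (-0.08, SE 0.04), Dlg2 (-0.07, SE 0.04) and Homer1 (-0.09, SE 0.06) and the glutamate receptor gene Grin2b (-0.21, SE 0.13). Without mouse 3 the excitatory synapse list no longer passed (adjusted p = 0.238), and in batch B alone its direction turned (0.686). Clock genes lay higher in males (13 of 15 positive, median 0.04; camera adjusted p = 0.0128, and adjusted p = 0.860 with an estimated correlation), with Cry2 at 0.08 (SE 0.03), Bhlhe41 at 0.12 (SE 0.06) and Per1 at 0.12 (SE 0.08), while Clock stood at -0.06 (SE 0.04). The thalamus and neighbouring region list also lay higher (11 of 12 positive, median 0.21; camera adjusted p = 0.0104, and adjusted p = 0.860 with an estimated correlation), with the forebrain transcription factor genes Nkx2-1 (0.24, SE 0.12), Lhx6 (0.09, SE 0.04) and Lef1 (0.12, SE 0.08), and Dlk1 (0.46, SE 0.33). Striatal interneuron genes did so too (12 of 17 positive, median 0.05; camera adjusted p = 0.0308, and adjusted p = 0.622 with an estimated correlation), with Slc18a3 at 0.17 (SE 0.08), Lhx8 at 0.20 (SE 0.11) and Trh at 0.15 (SE 0.09). Without the 4 mice of high cortical score the clock (adjusted p = 0.0566), thalamus (0.0637) and interneuron (0.228) lists did not pass, nor did clock in batch A alone (0.518) or thalamus (0.0797) and interneuron (0.567) in batch B alone. In these 5 lists 0 members passed, over all genes or adjusted over the list alone. Without mouse 12 the ribosomal (adjusted p = 0.000626) and microglial (0.0495) lists also passed, upwards in males. Among the lists that did not pass, Fcrls passed in the microglial list both ways, and adjusted over the list alone 1 inhibitory synapse gene was higher and 1 glucocorticoid responsive gene lower in males. The other lists had adjusted p from 0.0529 (ependyma) to 0.962 (opioid), and their median differed in sign from the mean or the test for actin, astrocyte, ribosomal, dopamine, inhibitory synapse, microglial, opioid and pan striatal genes.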

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

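All tests on mouse 3 were chosen only after its Xist value was seen, and list tests without mouse 12 after its scores were. Within groups of 8 mice, 15 of 132 combinations of a gene or list score and a group had 1 mouse far from the rest. This was measured by its gap to the nearest other mouse as a share of the group's range. Chance gives about 1 in 20 groups for independent, normally distributed values. The combinations are not independent, since some genes also belong to the lists and several flags fall on the same mice. No excess is read from this count.

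Mouse 3, labelled N/N female, stood apart from the other females in X-linked transcripts. Its log2 CPM was 0.35 for Xist, 3.10 for Eif2s3x and 4.05 for Gm2223, and its X-linked list score was -0.86. A male under a female label is argued against, since 4 of 4 Y-linked genes lay under the lowest male (62 counts in sum, against 4655 to 6762 in males and 6 to 156 in the other females). The mean log2 CPM of the 4 X-linked genes Kdm6a, Eif2s3x, Ddx3x and Kdm5c was 5.70, within the males (5.57 to 5.72) and under every other female (5.97 to 6.16), so a single X chromosome is a candidate explanation. Counts per gene do not show the karyotype, and loss of Xist with the inactive X was not tested apart from it.

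Other mice stood apart as follows. Mouse 5 (N/- male) was the lowest of its group in log2 CPM of Kdm5d (4.42), Uty (4.27) and 5530601H04Rik (2.86), and the highest in Pbdc1 (3.36) and in cholesterol synthesis score (0.17). Mouse 12 (N/- female) was the highest of its group in log2 CPM of Fcrls (5.42), in ribosomal protein score (0.52) and in microglial score (0.40). Of the 32 mice it also had the highest mitochondrial share (10.4%, the next 8.23%), the highest share of counts in the top 20 genes (14.2%) and the lowest TMM factor (0.931). Mouse 31 (N/N female) was the highest in log2 CPM of Myo3b (4.78), mouse 27 (N/N male) the lowest in Eif2s3y (4.10), and mouse 28 (N/N female) the highest in cholesterol synthesis score (0.33).

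The genotype effect differed between the sexes in 13 gene lists by camera with the preset correlation, and in 0 with an estimated correlation. The effect was more positive in males for immediate early genes (median difference 0.26, adjusted p = 1.29e-05), inhibitory synapse (0.06, 0.00422), striatal interneuron (0.11, 0.00422), myelin (0.07, 0.00967), thalamus and neighbouring regions (0.30, 0.00967), haemoglobin (0.40, 0.0115), excitatory synapse (0.06, 0.0118) and heat shock (0.09, 0.0247). It was more negative in males for Y-linked (-1.40, adjusted p = 0.00153), ribosomal protein (-0.09, 0.00235), X-linked (-0.09, 0.0169), cholesterol synthesis (-0.07, 0.0298) and microglial genes (-0.05, 0.0419). With an estimated correlation the adjusted p of these 13 lists was 0.445 to 0.694. In batch B alone the direction turned for myelin (adjusted p = 9.07e-07), haemoglobin (0.292) and immediate early genes (0.876), and in batch A alone for heat shock (0.534) and microglia (0.123). With cage as a random effect the heat shock (adjusted p = 0.0573), microglial (0.0900) and myelin (0.100) lists no longer passed. Without mouse 3 the cholesterol synthesis (adjusted p = 0.137), excitatory synapse (0.0886) and X-linked (0.207) lists no longer passed. Without mouse 12 the ribosomal protein (adjusted p = 0.337) and microglial (0.679) lists no longer passed, and the pan striatal (0.00234), D1 (0.0223) and dopamine signalling (0.0253) lists passed, more positive in males. The Y-linked difference rests on low counts in females. There Ddx3y was 0.965 ± 0.881 CPM in N/- and 0.381 ± 0.485 CPM in N/N mice (SD, n = 8 each). Females carry no Y chromosome, so this difference is not read as a genotype effect on Y-linked genes. Ddx3y stood at 2 to 64 counts per female, against 2200 to 3050 per male. In males Xist stood at 30 to 598 counts. Whether such counts are stray reads from mice of the other sex was not tested.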

How the results depend on the processing

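The settings with the cortical score as a covariate, without the 4 mice of highest cortical score, and list tests without mouse 3 or mouse 12 were chosen only after the data were seen. The cause of the changes below was not tested. DESeq2 gave 28 genes by sex (18 shared), surrogate variables 80 (18 shared), cage as a random effect 13 (13 shared) and batch A alone 7. The first run alone gave 1 gene by genotype in males, and batch B alone gave 5 by genotype. With an estimated correlation 0 lists passed by genotype, 2 by sex and 0 for the interaction. By sex 11 lists passed in batch A alone and 12 in batch B alone. Without the 4 mice 4 lists passed by sex and 8 for the interaction. Leaving out 1 mouse at a time gave 2 genes by genotype each time, a Cyfip2 log2 fold change of -0.85 to -0.81, and 16 (without mouse 12) to 22 genes (without mouse 9) by sex. Of list tests only 2 mice were left out, and without mouse 3 or mouse 12 in that order 9 and 10 lists passed by genotype, 7 and 9 by sex, and 10 and 14 for the interaction.

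These lists reversed, with adjusted p. In batch A alone they were cholesterol synthesis by sex (0.457), and heat shock (0.534) and microglia (0.123) for the interaction. In batch B alone they were excitatory synapse by sex (0.686), and haemoglobin (0.292), immediate early (0.876) and myelin (9.07e-07) for the interaction. By genotype they were cholesterol synthesis (0.880), ribosomal proteins (0.880) and microglia (0.943) with surrogate variables, cholesterol synthesis (0.587) and cortical neurons (0.680, where the list is its own covariate) with the cortical covariate, and cholesterol synthesis (0.605) without the 4 mice.

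Among values of genes named by the rule under the other settings, 12 no longer passed and 1 passed newly. Of 2143 such values 39 changed sign, 27 of them by at most 1 SE and 12 by more, all in genes that did not pass under either setting. Of 3385 values with 1 mouse left out 40 changed sign, all by at most 1 SE, and none changed its side of the threshold. These counts leave out the sex genes named beyond the rule (Uba1y, Chrdl1, Myo3b, Vdr and Tmem174), each of which lost its call under several settings. With 1 mouse left out, Vdr and Tmem174 both lost their calls without mouse 12, 17, 23 or 27, and 1 of them without some others. Of 320 values of the 32 list tests that passed, over 10 settings, 13 reversed, 106 kept their direction and no longer passed, and the rest kept direction and side of the threshold. Of 610 values of the list tests that had not passed, 74 passed under another setting. At this depth 1.2-fold changes were recovered for 56% of simulated genes by genotype and 11% for the interaction. These simulations changed many genes at once, which makes the adjusted threshold easier to reach. The real tests called 2 genes by genotype and 0 for the interaction, so recovery there may be lower than these shares.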

Other observations

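Tests chosen only after the result was seen were the relation of En2 to Cyfip2 and every test on tissue composition; those on the neighbours of En2 and on midbrain and hindbrain markers were prompted by the value of En2 and set before their own values were seen.

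En2 was higher in N/- mice by 1.32 on the log2 scale. A regional effect at En2 is argued against by its 6 tested neighbours within 1 Mb, with a median log2 fold change of 0.072 (SE 0.03). RNA from midbrain or hindbrain was examined with 19 markers of these regions with a count, of which Th, Ddc, Nr4a2 and Slc6a3 also stand in other lists or the striatum. Their median log2 fold change was 0.028 (SE 0.13), against a lower bound of 1.09 for En2. Several had too few counts over all 32 mice to show a rise (Fev 1, Foxa1 4, Pax7 5, Gabra6 8). Among better counted markers, Cbln1 (0.07, SE 0.17, 5.61 against 5.29 CPM), Tph2 (0.03, SE 0.15) and Cbln3 (0.43, SE 0.19) lay more than 2 SE below that bound. These values argue against such RNA as the source. Nr4a2 stood at 44.1 against 43.8 CPM. Cassette sequence transcribed from the targeted Cyfip2 allele may add En2 reads, since an En2 splice acceptor is a common part of targeting cassettes, but the design of the allele is not given in the sources used here. Over the 16 N/- mice Pearson r of En2 and Cyfip2 was 0.037 (permutation p = 0.894; Spearman rho 0.08, p = 0.769; adjusted p = 0.894 over 3 relations; r = 0.10 without the 2 mice farthest from the median), and -0.38 in batch A and 0.40 in batch B (exact permutation p = 0.481 for the 6 mice), so cassette transcription and a change of the En2 gene itself cannot be told apart by counts per gene.

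Projection neuron lists were lower and the cortical list higher in N/- mice. A lower share of projection neurons that raised all other cell types alike is not settled. The lowest of 4 other cell type scores was the endothelial one, at -2.41 standard errors (-0.08, SE 0.03). Its adjusted p was 0.351 over all lists by a linear model with batch and sex. The microglial (-0.04, SE 0.04), astrocyte (-0.0052, SE 0.04) and myelin (-0.0010, SE 0.08) differences were smaller than their SE, so these scores do not decide the question. More cortical tissue in some dissected pieces is a candidate explanation: with the cortical score as a covariate 0.362 of the difference in projection neuron score was left (-0.12, SE 0.07, became -0.04, SE 0.04), and the cortical score differed by 0.24 in each batch (SE 0.28 in A and 0.12 in B). Whether batch plays a part stays open. Lanes cannot be told apart from other differences between the mice of A and B, dissection included. With batch as a term the score difference was -0.12 (SE 0.07). The smaller within-batch difference was 0.256 of it, with -0.22 (SE 0.12) in A and -0.03 (SE 0.06) in B. In batch B alone the pan striatal list passed camera (adjusted p = 0.0430), while the D1 (0.194) and D2 (0.748) lists did not. The pan striatal list passed with the cortical covariate (adjusted p = 0.00352) but not with surrogate variables (0.316), nor over all mice with the correlation between genes estimated (adjusted p = 0.458 with an estimated correlation), so neither cortical tissue as the whole cause nor an effect of genotype on projection neurons is settled.

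The mice were split 100 times within batch and sex or genotype, the real split included. As many genes as in the real split came from 2 splits by genotype (2 genes, highest other 2) and 1 by sex (18 genes, highest other 1). Within males it was 1 split (2 genes, highest other 0), and within females 2 splits (2 genes, highest other 378). These counts include the targeted Cyfip2, and by sex the Y-linked genes and Xist. They therefore do not exclude chance for any other single gene. For the 0 interaction genes by edgeR (292 at an unadjusted p under 0.05, 0 by DESeq2 and limma voom) the count of splits says nothing about chance, since all 100 splits reach 0 (highest other 598). Chance could not be excluded for the 12 lists by genotype (22 splits; highest other 17), the 7 by sex (86 splits; highest other 20) and the 13 for the interaction (17 splits; highest other 17). The 2 single splits with 378 genes in females and 598 for the interaction gave many more than the real split, and what sets them apart was not tested.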
